A study of Homo sapiens with 6 samples.

How the data were processed

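Gene expression was measured on 6 arrays, 3 of control neural cells and 3 of isthmic organizer (IsO)-like cells. All were derived from H9, an established line of human embryonic stem cells. Per the labels' protocols, floating aggregates of H9 cells were neuralised for the first 4 days with 5 µM dorsomorphin and 10 µM SB431542, which block BMP and activin/TGF-beta receptors, then plated on day 4 and grown for another 5 days. For IsO-like cells the protocol adds FGF8 at 100 ng/ml and CHIR99021, a GSK3 inhibitor that activates Wnt signalling. The labels give CHIR99021 as a range from 0 to 1.2 µM. They do not say which concentration the arrayed cells had, or whether it was above 0. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be partly technical.

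Biotin-labelled RNA was hybridised to Illumina bead arrays. GenomeStudio 2011.1 is named in the submitters' processing notes. The deposited table held a linear intensity for each row and array, with no background subtracted, beside a detection p-value against the array's negative controls, per the file headers and the values. It had 34692 rows, 1 per gene name, so the authors had combined the probes of a gene before they deposited the values. By the spacing of the deposited detection p-values, 27322 rows held 1 probe and 7370 combined several. The planned choice of 1 probe per gene was therefore not needed, and disagreement between probes of a gene was not analysed here. The authors' processed table held log2 intensities of 34685 of these rows, with a column median of 7.23 on each array. It differed by at most 0.000408 from quantile-normalised log2 intensities without background correction, so its scale, centring and direction were known, and it served as an alternative. Rows carry the gene names of the array's design. In the RefSeq table of GRCh38.p14, used for names only, 17589 rows matched a current symbol, 2205 matched 1 gene by an older symbol, 119 matched several genes and 14779 had no match. No genome build was given in the sources used here, and no coordinates were used. Of 346 listed genes, 346 had a row, 2 of them under an older symbol.

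Intensities were background-corrected with the normexp model of limma 3.58.1 in R 4.3.3, with the spread of the negative controls inferred from the detection p-values, an offset of 16, quantile normalisation and log2. The inference was run on rows of 1 probe, since detection p-values of combined rows were on another scale. It gave background means of 122 to 132 and SDs of 22.3 to 27.8. Over all rows it gave means of 258 to 296 and SDs of 759 to 903, above the median intensity of every array, so that version became an alternative. Rows with a detection p-value below 0.05 on at least 3 of the 6 arrays were tested, which left 14548. A further 965 rows that combined several probes were not tested although their signal reached the lowest signal of a detected 1-probe row on at least 3 arrays; a setting that tests them too is among the alternatives. Quantile normalisation sets the arrays to 1 distribution, so a shift of most genes in a direction would not be seen, and differences of dim genes are compressed by the offset.

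IsO-like cells were compared with control cells by limma's moderated test (lmFit and eBayes), with no covariate, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Every adjusted p for a gene comes from that test unless the block is named. The 22 gene lists were fixed before the data were examined and tested with limma's camera, 2-sided, at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were run beside it. Members were also counted with p-values adjusted over the list alone. A row was taken as above background on an array at a detection p-value below 0.05, and a row of several probes also where its signal reached the lowest signal of a detected 1-probe row. Where a gene was not above background on any array of a group, its difference is given as at least N-fold. That bound sets the mean of the brighter group against the mean, per array of the dimmer group, of the higher of its own value and the lowest value of a detected 1-probe row. It holds only for the background correction used: it was lower without correction for all 13 genes that the rule took and that have such a bound, and 8 of the 9 called among them were still called. With the background from all rows it was also lower for all 13, and 2 of the 9 were called. Where a gene was above background on 1 or 2 arrays of a group, the number is given, and its difference includes values at background. For all 14 such genes the difference was smaller under both of these settings.

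Genes are named by a rule that was also fixed before the data were examined. It takes the 12 highest and 12 lowest differences among called genes whose groups did not overlap, leaving out names of no established function and genes excluded for privacy. In each list it takes up to 4 called members and up to 2 members that were tested and not called, by the size of the difference, and it always takes a further set that includes FGF8, WNT1, EN1, EN2, PAX2, PAX5, LMX1B, GBX2, OTX2, SIX3, SOX1, SOX2, PAX6, POU5F1, NANOG, AXIN2, SPRY4 and HOXA2. Listed genes not above background in either group may be said to be so. Not every gene the rule takes is printed here, though list tests and counts hold them all. Other genes are said to have been chosen after their values were seen.

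Control and IsO arrays share the numbers 1 to 3 in the labels. Deviations from the group means correlated between same-numbered arrays over the tested rows, at Pearson r = 0.871, 0.398 and 0.657 for numbers 1, 2 and 3. All 3 exceeded the minimum of 0.1 set for taking the numbers as pairs. Differently numbered arrays did so too, control 2 with IsO 3 at 0.701 and control 3 with IsO 2 at 0.491. The values thus set the arrays numbered 1 apart, but do not show which of those numbered 2 and 3 belong together. For these, pairing rests on the shared numbers alone, and the labels do not say what a number marks. A fit with the replicate number as a block was run as an alternative, and its value stands beside results whose call it changed. No pair of arrays held identical values.

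The test was checked on simulated data with the means, residual spread and replicate deviations of the 14548 rows, in which 200 genes were changed. Without the block it recovered 0% of genes changed by 1 on the log2 scale, 46.3% of those changed by 2 and 83.3% of those changed by 3, and called 0 unchanged genes. With the block it recovered 29.9%, 68.7% and 84.8%, and called 1 unchanged gene. In that simulation same-numbered arrays shared their deviations by construction, which favours the block. Data simulated without replicate deviations gave higher recovery without the block. There the test recovered 58.2%, 86.6% and 97.0% without the block and called 7 unchanged genes. With the block it recovered 23.9%, 74.6% and 87.9% and called 1 unchanged gene. Of 50 sets of 12 genes simulated with the replicate deviations, camera called 10 of the 10 that were shifted by 1 and 1 of those that were not. These sets were random genes with residuals drawn independently, so this check does not cover lists whose genes vary together. Alternatives covered the background correction, the offset, the normalisation, the authors' table, the filter on dim rows, the variance model, array weights, the replicate block, the set test and each array left out. Alternatives chosen after seeing the data were the background from all rows, the wider filter, a batch term for the arrays numbered 1, leaving those arrays out and array weights by another method.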

Results

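The arrays compared isthmic organizer (IsO)-like cells with control neural cells, both made from the H9 embryonic stem cell line. The isthmic organizer is the signalling centre at the boundary between midbrain and hindbrain. The comparison addresses how cells under the FGF8 and CHIR99021 protocol differed from the control cells in regional and signalling genes. For CHIR99021 the labels give only a range from 0 to 1.2 µM. Each group had 3 arrays. Median intensities were 144, 152 and 146 on the control arrays and 153, 147 and 157 on the IsO arrays, and between 13999 and 15232 of the 34692 rows had a detection p-value below 0.05 on an array. The number of arrays limits the precision. The main fit has no term for the replicate number, so shifts shared by same-numbered arrays also add to its standard errors.

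Genes of the isthmic organizer rose in IsO-like cells. EN1 and EN2, homeobox genes of the midbrain-hindbrain region, were at least 23.1-fold (adjusted p = 0.00105) and at least 9.69-fold (adjusted p = 0.00323) higher, and were not above background on any control array. Without background correction these bounds were 8.68-fold and 4.05-fold, and with the background from all rows 1.96-fold and 1.27-fold, where neither gene was called. WNT1, a secreted signal of the organizer, rose by 3.65 ± 0.30 on the log2 scale (SE, 3 arrays per group, adjusted p = 0.00364), and FGF17, an FGF family member made there, by 5.20 ± 0.24 (adjusted p = 0.000592). The difference of FGF17 ranged from 1.91 to 5.48 over the alternatives, and it was not called with the background from all rows. PAX8, a paired-box factor, was at least 8.03-fold higher (adjusted p = 0.0135), or 3.52-fold without background correction and 1.23-fold, not called, with the background from all rows. These were the 5 of 9 tested members of the isthmic organizer list that rose, none fell and 4 did not pass, and adjusted over the list alone, 5 rose and 1 fell. With the replicate block 6 rose and 1 fell. The list was higher as a set (camera, adjusted p = 5.34e-10, median log2 difference 3.61, or 3.00 with genes below background at their bound, adjusted p = 0.107 with an estimated correlation). FGF8 itself differed by 0.96 ± 0.46 (adjusted p = 0.609, 0.0418 with the replicate block), and SP8 by -1.55 ± 0.48 (adjusted p = 0.295, 0.0314 with the block). PAX5 was not above background on any array, and PAX2 and LMX1B were above it on 1 IsO array each, so they were not tested.

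**Figure D1:**
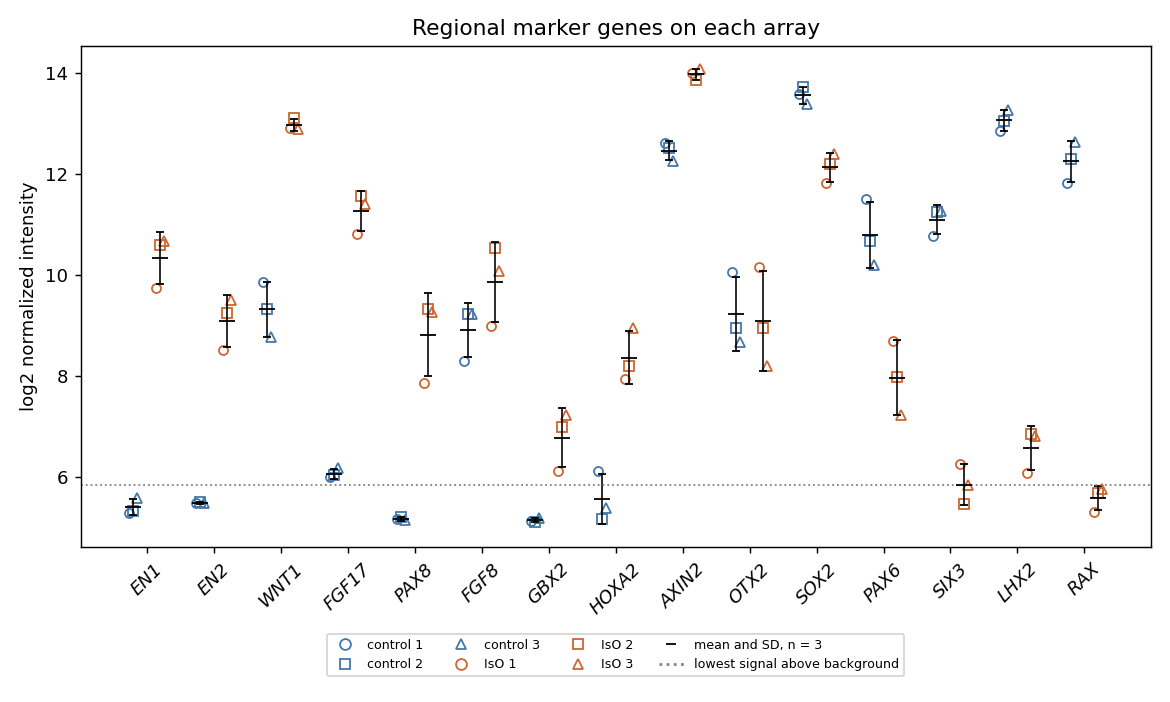
Log2 normalised intensity (vertical axis) of 15 marker genes on each of the 3 control (blue) and 3 IsO (orange) arrays; black marks give the mean and SD of 3 arrays, symbols the replicate number, and the dotted line the highest among the arrays of the lowest value above background. EN1 averaged 5.41 on control and 10.35 on IsO arrays, while RAX averaged 12.26 and 5.58.

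Forebrain genes fell. RAX, a homeobox gene of the eye field, was at least 90.0-fold lower in IsO-like cells (adjusted p = 0.000570) and was not above background on any IsO array; without background correction the bound was 31.2-fold, and with the background from all rows 9.34-fold. LHX2, SIX3 and FEZF2, transcription factors of the anterior neural plate, differed by -6.48 ± 0.27, -5.25 ± 0.27 and -4.97 ± 0.26 on the log2 scale (SE, 3 arrays per group, adjusted p = 0.000570, 0.000690 and 0.000690). SIX3 was above background on 2 of the 3 IsO arrays. It differed by -3.81 without background correction and -1.70 with the background from all rows, called under both. The smallest differences of LHX2 and FEZF2 over the alternatives were -4.16 and -1.98. Of 16 tested members of the forebrain list, 12 fell, 4 did not pass and none rose, and adjusted over the list alone, 15 fell, and with the block 14 fell. As a set the list was lower (camera, adjusted p = 9.09e-36, median -3.12, or -2.79 with bounds, adjusted p = 0.0469 with an estimated correlation). HESX1 was at least 2.55-fold lower (adjusted p = 0.0617, 0.0308 with the block) and BARHL2 at least 1.39-fold lower (adjusted p = 0.0986, 0.0310 with the block), neither past the threshold without the block.

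Hindbrain genes were higher as a set (camera, adjusted p = 4.93e-14, median 1.64, or 1.08 with bounds, adjusted p = 0.0662 with an estimated correlation). HOXA2, the HOX gene with the most anterior expression limit in the hindbrain, rose by 2.80 ± 0.36 (SE, 3 arrays per group, adjusted p = 0.0231), or 1.59 without background correction and 0.20 with the background from all rows, where it was not called, and was above background on 1 control array. IRX2 rose by 1.59 ± 0.25 (adjusted p = 0.0413) and CDX2, a posterior homeobox gene, was at least 1.90-fold higher (adjusted p = 0.0445), a call that was lost without background correction and with the background from all rows. Of 11 tested members, 3 rose and 8 did not pass, and adjusted over the list alone 11 rose. With the replicate block 8 rose. GBX2, which marks the hindbrain side of the organizer, was at least 1.95-fold higher (adjusted p = 0.0720, 0.0288 with the block). IRX3 differed by 1.89 ± 0.34 (adjusted p = 0.0650, 0.0276 with the block). Of listed members chosen here after their values were seen, HOXB2 was at least 1.93-fold higher (adjusted p = 0.0963, 0.0111 with the block), while HOXA3, HOXA4, HOXB1, HOXB3 and HOXB4 were not above background on any array.

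Members of the midbrain list moved both ways. PAX3, a dorsal neural tube factor, was at least 2.38-fold higher (adjusted p = 0.0182). Without background correction it was 1.50-fold, and with the background from all rows 1.04-fold and not called. DMRTA2 and BARHL1 changed by -4.15 ± 0.20 and -2.88 ± 0.26 on the log2 scale (SE, 3 arrays per group, adjusted p = 0.000592 and 0.00693). DMRTA2 was above background on 2 IsO arrays. It differed by -2.76 without background correction and -0.67 with the background from all rows, called under both. Of 9 tested members 1 rose, 2 fell and 6 did not pass, and adjusted over the list alone 3 rose and 2 fell. With the block 4 rose and 2 fell. The list was not called (camera, adjusted p = 0.392, median 0.42, mean 0.03), but fry called it lower (adjusted p = 0.0353, the lowest of all alternatives, the highest being 0.866). OTX2, which marks forebrain and midbrain, differed by -0.13 ± 0.58 (adjusted p = 0.994). DMBX1 and POU4F1 differed by 2.77 ± 0.55 and 1.78 ± 0.30 (adjusted p = 0.0867 and 0.0510, 0.0134 and 0.0111 with the block).

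Targets of Wnt/beta-catenin signalling, the pathway that CHIR99021 activates, rose, in a list that also holds the ligand genes WNT3A and WNT8B. SP5, a direct target, rose by 3.92 ± 0.27 on the log2 scale (SE, 3 arrays per group, adjusted p = 0.00204), APCDD1 and NKD1, which are feedback inhibitors, by 3.48 ± 0.21 and 2.79 ± 0.18 (adjusted p = 0.00123 and 0.00131), WNT3A by 3.23 ± 0.44 (adjusted p = 0.0273) and AXIN2 by 1.51 ± 0.18 (adjusted p = 0.0190). These were the 5 of 11 tested members that rose; 6 did not pass, and adjusted over the list alone 8 rose and 1 fell. With the block 7 rose and 1 fell. The list was higher (camera, adjusted p = 6.35e-11, median 1.51, adjusted p = 0.0469 with an estimated correlation). LEF1 and ZNRF3 differed by 1.79 ± 0.39 and 1.15 ± 0.25 (adjusted p = 0.119 and 0.117, 0.0141 and 0.0287 with the block).

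None of 10 tested genes of FGF feedback passed, and adjusted over the list alone 1 rose. With the block 1 rose and 1 fell. The FGF list was not called (camera, adjusted p = 0.400, median 0.29). SPRY2 differed by 1.01 ± 0.21 on the log2 scale (SE, 3 arrays per group, adjusted p = 0.104, 0.0370 with the block), SPRY4 by 0.83 ± 0.40 (adjusted p = 0.613) and FGFRL1 by -1.37 ± 0.45 (adjusted p = 0.332, 0.0291 with the block).

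Targets and ligands of BMP and TGF-beta signalling were higher as a set (camera, adjusted p = 2.31e-06, median 0.97, adjusted p = 0.0469 with an estimated correlation). MSX2 and MSX1, homeobox genes of the dorsal midline, rose by 3.53 ± 0.36 and 2.99 ± 0.47 (SE, 3 arrays per group, adjusted p = 0.00978 and 0.0431) and ID1 by 1.94 ± 0.23 (adjusted p = 0.0179), with MSX2 above background on 2 control arrays, while ID4 fell by 1.62 ± 0.25 (adjusted p = 0.0381). MSX2 differed by 2.485 without background correction and by 0.66, not called, with the background from all rows. Of 11 tested members 4 rose, 1 fell and 6 did not pass, and adjusted over the list alone 7 rose and 2 fell. With the block 6 rose and 1 fell. ID2 differed by 1.91 ± 0.45 (adjusted p = 0.145, 0.0135 with the block) and LEFTY2, above background on 1 IsO array, by -1.01 ± 0.31 (adjusted p = 0.277).

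Retinoic acid genes were higher as a set, though not with the replicate block (camera, adjusted p = 0.00872, 0.0801 with the block and 0.00284 to 0.138 over all alternatives, median 0.80, adjusted p = 0.118 with an estimated correlation). CYP26A1, which degrades retinoic acid, rose by 2.74 ± 0.45 (SE, 3 arrays per group, adjusted p = 0.0481), or 1.63 without background correction and 0.25 with the background from all rows, neither called, and was above background on 1 control array. STRA6, which takes up retinol, rose by 2.25 ± 0.21 (adjusted p = 0.00693). Its difference ranged from 0.24 to 2.35 over 21 alternatives, and it was called under 20 of them. ALDH1A2, which makes retinoic acid, fell by 2.17 ± 0.28 (adjusted p = 0.0225) and was above background on 1 IsO array. It differed by -1.12 without background correction and -0.11 with the background from all rows, neither called. Of 9 tested members 3 rose, 1 fell and 5 did not pass, and adjusted over the list alone 5 rose and 2 fell, as many as with the block. CRABP1 and ALDH1A3 differed by 1.55 ± 0.31 and -1.09 ± 0.28 (adjusted p = 0.0876 and 0.196, 0.00856 and 0.0170 with the block), the latter above background on 1 IsO array.

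Genes of neurons rose as a set (camera, adjusted p = 4.93e-14, median 1.37, adjusted p = 0.0708 with an estimated correlation). NEUROG1, a proneural factor, rose by 2.47 ± 0.24 (SE, 3 arrays per group, adjusted p = 0.00798), or 1.35 without background correction and 0.16 with the background from all rows, where it was not called, and was above background on 1 control array. NEFM, a neurofilament subunit, rose by 2.67 ± 0.44 (adjusted p = 0.0498), a call lost under both of these settings. SYT4 was at least 4.17-fold higher (adjusted p = 0.0135), or 2.13-fold without background correction and 1.09-fold, not called, with the background from all rows. Of 17 tested members 6 rose, 1 fell and 10 did not pass, and adjusted over the list alone 11 rose and 1 fell. With the block 10 rose and 1 fell. Of members chosen here after their values were seen, STMN4 differed by -1.76 ± 0.23 (adjusted p = 0.0252). DCX, TUBB3, MAP2 and STMN2, chosen likewise, differed by 0.33, 0.51, 0.52 and 1.61 and did not pass (adjusted p = 0.880, 0.464, 0.607 and 0.732). ISL1 and GAP43 differed by 2.02 ± 0.75 and 1.86 ± 0.45 (adjusted p = 0.419 and 0.154, 0.0423 and 0.0179 with the block), with ISL1 above background on 1 control array. This list was also higher on the arrays numbered 1 than on the other arrays, in both groups together (camera, adjusted p = 0.0125, 0.617 with an estimated correlation).

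Among genes of neural progenitors, SOX2, a stem and progenitor factor, fell by 1.43 ± 0.22 on the log2 scale (SE, 3 arrays per group, adjusted p = 0.0384). Of 16 tested members 1 rose, 1 fell and 14 did not pass, and adjusted over the list alone 1 rose and 2 fell. With the block 1 rose and 3 fell. The list was not called (camera, adjusted p = 0.105, median -0.35), but fry called it lower (adjusted p = 0.00798, the lowest of all alternatives, the highest being 0.368). PAX6 differed by -2.82 ± 0.47 (adjusted p = 0.0521, 0.00222 with the block) and SOX21 by -1.71 ± 0.62 (adjusted p = 0.407). SOX1 was above background on 1 IsO array and no control array, and was not tested. In the Notch list, DLL3, a Notch ligand family member, rose by 2.32 ± 0.18 (adjusted p = 0.00325) and 10 of 11 tested members did not pass, and adjusted over the list alone 2 rose and 3 fell, and with the block 2 rose and 2 fell. HES5 and DLL1 differed by -1.32 ± 0.33 and -1.19 ± 0.35 (adjusted p = 0.168 and 0.256, 0.0218 and 0.0281 with the block). The Notch list had a median of -0.47 and a mean of -0.02, against an upward direction in camera (adjusted p = 0.982). None of 4 tested Hedgehog genes passed, and none passed when adjusted over the list alone. That list had a median of -0.01 and a mean of 0.06, with an upward direction in camera (adjusted p = 0.982); GLI1 and PTCH1 differed by 0.89 ± 0.58 and -0.65 ± 0.57 (adjusted p = 0.787 and 0.888). GLI1 was above background on 1 control and 2 IsO arrays.

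Markers of neural crest were higher as a set (camera, adjusted p = 0.00643, median 0.83, adjusted p = 0.321 with an estimated correlation). The call was lost without IsO 1 (adjusted p = 0.390) and in the arrays numbered 2 and 3 alone (adjusted p = 0.0735), and it ranged from 6.98e-05 to 0.390 over all alternatives. The list was higher on the arrays numbered 1 than on the others (camera, adjusted p = 0.0125, 0.617 with an estimated correlation), and fry did not call the list higher in IsO-like cells (adjusted p = 0.180). TWIST1 rose by 1.97 ± 0.31 (SE, 3 arrays per group, adjusted p = 0.0449) and 10 of 11 tested members did not pass, and adjusted over the list alone 3 rose, and with the block 5 rose. TFAP2A and SNAI2 differed by 1.91 ± 0.50 and 1.82 ± 0.67 (adjusted p = 0.192 and 0.410, 0.0217 and 0.0162 with the block), with TFAP2A above background on 1 control array.

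The remaining lists were not called by camera. Of pluripotency genes, 6 were tested and none passed by either adjustment (camera, adjusted p = 0.155, median -0.36); USP44 and L1TD1 differed by -1.06 ± 0.46 and -0.86 ± 0.91 (adjusted p = 0.539 and 0.921), L1TD1 was above background on 1 IsO array, NANOG was not above background on any array and POU5F1 was above it on 1 IsO array. Of 4 tested mesoderm and endoderm genes none passed, 2 rose adjusted over the list alone and 1 with the block (camera, adjusted p = 0.0507); MESP1, above background on 2 control arrays, differed by 1.62 ± 0.30 (adjusted p = 0.0720, 0.0101 with the block) and HAND1 was at least 1.80-fold higher (adjusted p = 0.234). Of 9 mesenchyme genes none passed, 1 rose adjusted over the list alone, and with the block 1 rose and 1 fell (camera, adjusted p = 0.464); COL3A1 and COL1A2 differed by 1.55 ± 0.34 and 1.24 ± 0.55 (adjusted p = 0.117 and 0.551, 0.0351 with the block for COL3A1). Of 6 genes of surface ectoderm and placodes none passed by either adjustment (camera, adjusted p = 0.270); KRT19 and TFAP2C differed by -0.90 ± 0.25 and 0.88 ± 0.60 (adjusted p = 0.226 and 0.802). Of glial genes 2 were tested and none passed, with 1 higher when adjusted over the list alone or with the block (camera, adjusted p = 0.105); S100A10 and SLC1A3 differed by 2.16 ± 0.43 and 0.13 ± 0.71 (adjusted p = 0.0877 and 0.994, 0.0174 with the block for S100A10).

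None of 17 tested cell cycle genes passed by either adjustment (camera, adjusted p = 0.860, downward, against a median of 0.05 and a mean of -0.04); CENPF and TOP2A differed by -0.75 ± 0.58 and -0.62 ± 0.60 (adjusted p = 0.856 and 0.906). The cell cycle list, too, was higher on the arrays numbered 1 than on the others (camera, adjusted p = 0.0125, 0.617 with an estimated correlation). Of 11 genes of hypoxia and glycolysis, ALDOC, a glycolytic aldolase, rose by 1.45 ± 0.17 (adjusted p = 0.0179) and 10 did not pass, and adjusted over the list alone, and also with the block, 2 rose and 1 fell (camera, adjusted p = 0.0529; fry called the list higher, adjusted p = 0.00798, the lowest of all alternatives, the highest being 0.212). EGLN3 and BNIP3 differed by -1.72 ± 0.35 and 0.86 ± 0.18 (adjusted p = 0.0937 and 0.0992, 0.0201 and 0.0314 with the block). None of 17 cellular stress genes passed by either adjustment, and with the block 1 rose and 2 fell (camera, adjusted p = 0.170); JUN and ASNS differed by -1.50 ± 0.42 and 1.14 ± 0.34 (adjusted p = 0.227 and 0.277, 0.0108 and 0.0499 with the block). None of 15 ribosomal protein and translation genes, the control list, passed by either adjustment (camera, adjusted p = 0.322); RPL13 and RPLP0 differed by 0.34 ± 0.19 and 0.32 ± 0.17 (adjusted p = 0.706 and 0.682).

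**Figure D2:**
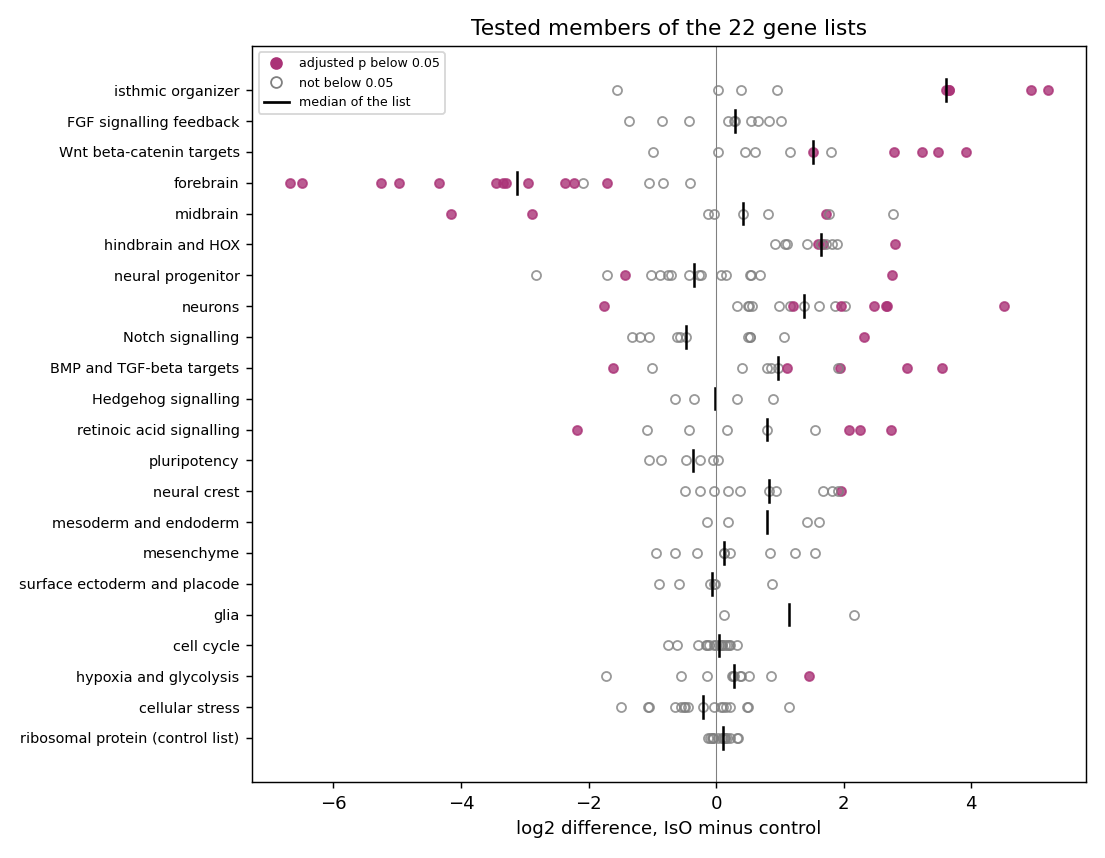
Log2 difference of IsO minus control (horizontal axis) of every tested member of the 22 gene lists (rows); filled points have an adjusted p below 0.05 in limma, open points do not, and black bars give each list's median. The forebrain list has its median at -3.12 and the isthmic organizer list at 3.61.

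Outside the lists, FOXQ1, a forkhead factor, was at least 25.9-fold higher in IsO-like cells (adjusted p = 0.000570), or 9.65-fold without background correction and 2.10-fold, not called, with the background from all rows, and OLIG3, a factor of dorsal hindbrain progenitors, rose by 3.89 ± 0.63 on the log2 scale (SE, 3 arrays per group, adjusted p = 0.0453). FZD5, a Wnt receptor, and SHISA2, an antagonist of Wnt and FGF receptors, changed by -4.60 ± 0.28 and -3.98 ± 0.21 (adjusted p = 0.00121 and 0.000690). CCKBR, the cholecystokinin B receptor, and DRD4, a dopamine receptor, changed by -4.10 ± 0.52 and -3.66 ± 0.21 (adjusted p = 0.0225 and 0.00105), and IGFBP3, a carrier of insulin-like growth factors, fell by 3.41 ± 0.55 (adjusted p = 0.0467).

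In all, 119 genes were higher and 71 lower in IsO-like cells among the 14548 tested, 118 and 71 of them by at least 1 on the log2 scale. With the replicate block 481 were higher and 371 lower, and these included all 190 genes called without it. With the background from all rows 62 were higher and 39 lower, and 25 of the 46 called genes that the rule took lost their call, among them FGF17, EN1, EN2, PAX8, FOXQ1, OLIG3, FEZF2, FZD5, IGFBP3, HOXA2, CDX2, IRX2, PAX3, SOX2, SYT4, NEFM, NEUROG1, MSX1, MSX2, ID1, ID4, CYP26A1, ALDH1A2 and TWIST1. Under that setting the background mean lay above the median intensity of every array. The 3 values of each group lay apart for 2246 genes, 15.4% of those tested, where chance gives 10% if the 6 arrays are exchangeable, which paired arrays are not, and for 190 of the 190 called. Camera called 8 of the 22 lists, of which the forebrain, Wnt target and BMP lists held with an estimated correlation.

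The arrays numbered 1 stood apart in both groups. The first principal component, 59.8% of the variance, separated control 1 and IsO 1 from the other 4 arrays, and the second, 27.7%, separated IsO from control. With the group in the model, 2645 genes were higher and 4023 lower on the arrays numbered 1 (limma, adjusted p below 0.05). In the arrays numbered 2 and 3 alone, 200 genes were higher and 166 lower in IsO-like cells, and 162 of the 190 genes were called there in the same direction. Leaving out any of the other 4 arrays lowered the counts more than leaving out one numbered 1. The genes higher and lower were 22 and 24 without control 2, 20 and 22 without control 3, 20 and 20 without IsO 2, 31 and 26 without IsO 3, 67 and 64 without control 1, and 108 and 53 without IsO 1. Of the 46 called genes that the rule took, 20 were called with each of the 6 arrays left out, among them EN1, EN2, WNT1, FGF17, RAX, LHX2 and SIX3; the calls of CDX2, IGFBP3 and SOX2 were lost whichever array was left out. The others lost their call without at least 1 of the arrays, among them PAX8, HOXA2, AXIN2, WNT3A and MSX1.

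**Figure D3:**
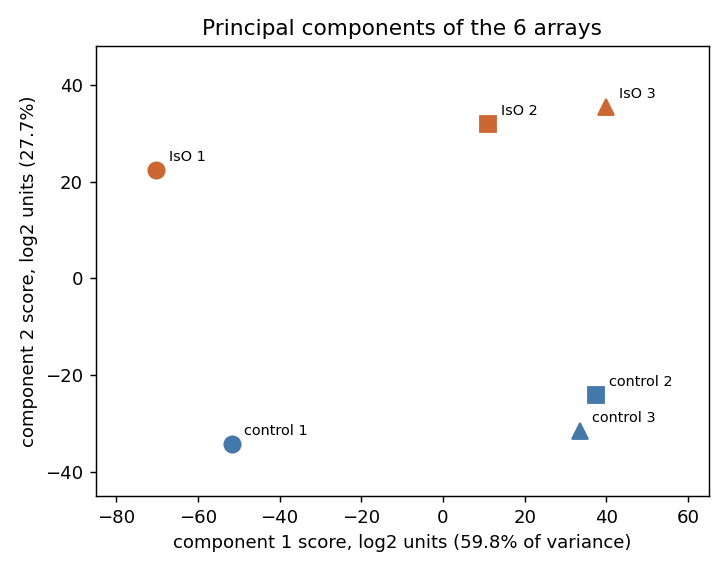
Scores of the 6 arrays on the first (horizontal, 59.8% of the variance) and second (vertical, 27.7%) principal components of the log2 intensities of the tested genes; blue points are control and orange points IsO arrays, and each point is 1 array. Control 1 and IsO 1 lie at the left, at -51.8 and -70.2, and IsO 3 lies farthest to the right, at 40.0.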

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

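Alternatives chosen after seeing the data are the background from all rows, the wider filter, the batch term, the arrays numbered 2 and 3 alone and the gene-by-gene weights. The 46 called genes that the rule took kept their direction wherever they were tested under the 21 alternatives that refit the genes. Over 1946 comparisons of the 93 named genes that were tested, 1596 kept their side of the threshold, 165 lost a call, 185 gained one and 0 called genes changed sign, with 8 sign changes among genes not called. Over 506 comparisons of the lists, 466 kept their side of the threshold, 15 lost a call, 24 gained one and 1 was called in the reverse direction. In 27 comparisons a list that was not called changed sign. The forebrain, Wnt target and BMP lists were called under all alternatives. For the changes given here the cause was not tested, except that fewer arrays were used where arrays were left out.

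Against 119 genes higher and 71 lower, cyclic loess gave 184 and 135, background from all rows 62 and 39 (it ended the calls of 25 named genes, EN1 and EN2 among them), a batch term for the arrays numbered 1 gave 655 and 597, and the arrays numbered 2 and 3 alone 200 and 166. The replicate block gave 481 and 371; it ended the call of the retinoic acid list (adjusted p = 0.0801) and changed no other list's, and among the named genes it added 30 calls and ended 0. Array weights gave 2325 and 2276, but their estimate stopped before it converged and put a weight of 71.0 on IsO 2 against 0.137 to 1.46 on the others; gene-by-gene weights gave 899 and 954. Leaving out each array in turn gave 20 to 108 higher and 20 to 64 lower.

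Camera called 8 lists, and 3 with an estimated correlation. That ended the calls of the isthmic organizer (adjusted p = 0.107), hindbrain (0.0662), neuron (0.0708), retinoic acid (0.118) and neural crest lists (0.321). With fry the midbrain list turned from higher, not called, to lower (0.0353), neural progenitor and hypoxia were called (0.00798 each) and neural crest was not (0.180). The retinoic acid call also ended with no filter (0.138), array weights (0.124; gene by gene 0.0720) and the batch term (0.0532). Neural crest ended with array weights (0.249; gene by gene 0.118) and in the arrays numbered 2 and 3 alone (0.0735). Hypoxia gained a call with no background correction (0.0206), offset 50 (0.0350), the authors' table (0.0204), no filter (0.0108), the trended robust variance (0.0145) and background from all rows (0.00909). Mesoderm and endoderm gained one with median scaling (0.0482), the stricter filter (0.0274), the trended robust variance (0.0342) and the wider filter (0.0493), and glia with the stricter filter (0.0316). Pluripotency was called as lower with array weights (0.0307; gene by gene 0.0384) and in the arrays numbered 2 and 3 alone (0.0173). With each array left out, adjusted p ranged from 0.0249 to 0.155 for mesoderm and endoderm, 0.0182 to 0.248 for neural progenitor, 0.0300 to 0.382 for pluripotency, 0.0443 to 0.307 for glia and 0.000101 to 0.390 for neural crest. Without IsO 1 the neural crest call was lost, and neural progenitor, pluripotency, and mesoderm and endoderm were called. Mesoderm and endoderm was also called without control 2, control 3 or IsO 2, and glia without IsO 2 or IsO 3.

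Other probes of a gene could not be chosen, since each gene had 1 row, and no slide was named, so those alternatives were not run. Of 346 listed genes 232 were tested. A further 16, rows of several probes, reached the signal of detected rows but were left out by their detection p-values, and are tested with the wider filter. The other 98 did not pass either filter on at least 3 arrays, though some, such as FOXA2 and FOXD3, were above background on fewer.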

Other observations

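Tests in this part that were chosen after the result was seen are the correlation of deviations, the correlation with gene span and the interaction. The gene families and the genes named in this part that the naming rule did not take were also chosen after their values were seen.

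Frizzled receptor genes, which encode receptors of Wnt signals, changed in both directions. Of 9 tested Frizzled receptor genes, FZD10 rose by 3.01 ± 0.28 on the log2 scale (SE, 3 arrays per group, adjusted p = 0.00696), while FZD5 and FZD8 changed by -4.60 ± 0.28 and -2.07 ± 0.28 (adjusted p = 0.00121 and 0.0255); the other 6 did not pass. With the replicate block 1 Frizzled gene rose and 3 fell. The smallest differences of FZD10, FZD5 and FZD8 over the alternatives were 0.57, -1.36 and -0.47. Of 9 tested WNT genes 3 rose: WNT1, WNT3A and WNT10B, the last by 2.25 ± 0.22 (adjusted p = 0.00920). With the replicate block 5 WNT genes rose and 2 fell. WNT5B, a row of several probes that was above background on all 6 arrays and left out by the detection filter, went the other way: with the wider filter it differed by -2.40 ± 0.39 (adjusted p = 0.0471), and 3 of 10 WNT genes rose and 1 fell. All 3 tested genes of the DMRT family fell. DMRTA1 fell by 3.21 ± 0.22 (adjusted p = 0.00191) beside DMRTA2, and DMRT3, not above background on any IsO array, was at least 4.29-fold lower (adjusted p = 0.00204). CCK, the ligand of CCKBR, was at least 2.67-fold lower (adjusted p = 0.0201). Without background correction the bounds of DMRT3 and CCK were 2.15-fold and 1.60-fold, and with the background from all rows 1.09-fold and 1.04-fold, where neither was called. GPC3, a cell surface proteoglycan, and DLK1, a transmembrane relative of Notch ligands, changed by -2.85 ± 0.21 and -3.10 ± 0.40 (adjusted p = 0.00241 and 0.0231). Apart from WNT5B, for which this was not computed, each gene named here kept its sign under the 21 alternatives that refit the genes, the other scalings included, and GPC3 was called under 21 of them, FZD5, FZD10, DMRTA1 and DMRT3 under 20, FZD8 and WNT10B under 16, DLK1 under 15 and CCK under 14.

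The real grouping gave 190 called genes in limma, and each other split of the 6 arrays into 3 and 3 gave 0, so 1 of the 10 splits, the real one, reached 190. Every other split mixes control and IsO arrays on both sides, so the IsO difference adds to its residual spread and works against calls there. At an unadjusted p under 0.05 the real grouping gave 1445 genes and the other splits 42 to 3821, the highest for control 1, IsO 1 and IsO 2 against the rest, which keeps the arrays numbered 1 together. For the lists, the real grouping called 8 and the highest other split also called 8, so 2 of the 10 splits reached that count. With 10 splits no share under 0.05 can be had. The split that also called 8 lists exchanged control 1 and IsO 1 and, like the real one, parted all 3 pairs. With the replicate block, the 4 splits that part all pairs gave 852 genes and 7 lists for the real grouping and at most 0 genes (398 at an unadjusted p under 0.05) and 4 lists for the others. Splits that part 1 pair called at most 6 lists.

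The arrays numbered 1 differed from the other 4 in both groups. A fault of 1 array is argued against by the deviations of control 1 and IsO 1 from their group means, which correlated at r = 0.871 over the tested genes. A different growth state or cell mix of these cultures stays open: camera called 3 lists as higher there (neurons, neural crest and cell cycle) and 0 with an estimated correlation (1 at an unadjusted p under 0.05). RNA quality or labelling may also play a part, as the shift correlated with genomic span (Spearman 0.239 across 10313 genes, which are not independent replicates), but cannot be told apart from cell state, because span is not transcript length and long neuronal genes would give the same sign.

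The higher neural crest list may reflect the arrays numbered 1 or crest cells among the IsO-like cells. In the arrays numbered 2 and 3 alone the direction held and the call did not (camera, adjusted p = 0.0735), with list medians of 1.25, 0.31 and 0.69 in pairs 1, 2 and 3. No test of whether crest cells were present is given here. The list stayed called with the replicate block (adjusted p = 0.00526) and with a batch term for the arrays numbered 1 (0.00241), but a shift shared by both arrays of a number cancels from the difference in this balanced design, so these fits do not test whether IsO 1 differed from its partner. Neither explanation is settled, and a difference between the groups in genes that crest and other neural cells share stays open, untested.

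A further hypothesis was that the IsO effect differed between pair 1 and pairs 2 and 3. In limma, 0 genes passed the interaction of group and pair, with 580 of 14548 at an unadjusted p under 0.05, or 3.99%. This has 2 residual degrees of freedom and does not show that the pairs responded alike. FOXA2, a floor plate gene, was at 4.87, 7.22 and 7.58 on IsO 1, 2 and 3 and 4.92 on average in control cells, above background on IsO 2 and IsO 3 only. NKX2-2, a ventral neural tube gene, was at 5.43, 6.40 and 7.31 on the same arrays. FOXD3, a crest gene, went the other way at 7.66, 5.27 and 5.27, above background on IsO 1 only.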
